A study of Homo sapiens with 3 samples.

How the data were processed

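Total RNA from SH-SY5Y cells infected with a GFP adenovirus was converted to biotin-labelled cRNA and hybridized to bead arrays, 1 array per sample, per the labels' protocols. Infection lasted 48 h, and RNA was set to 200 ng per microlitre before labelling. The 3 samples fall into 1 group, the GFP adenovirus, with replicate numbers taken from the sample titles. The study's other arm, a virus carrying GFP and PGC-1α, was not analysed here, so no comparison between groups was made.

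The deposited values are probe intensities on a linear scale, made with GenomeStudio per the submitters' processing notes. The version, the normalization, the treatment of background and the array model are not given in the sources used here. From the values themselves, the arrays had been normalized between each other with a quantile-like method: the sorted values of the 3 arrays differed from their mean by at most 0.037 on the log2 scale, and 47338 values occurred on all 3 arrays. The 3 columns together held 49562 distinct values, 759 more than the 48803 probes in the table; whether further rows entered the normalization or its handling of ranks made these values was not tested. No value was 0 or below, none was missing, and no probe number was repeated. A normalization of this kind forces the same intensity distribution on each array, so a difference in total signal or in the number of expressed genes between samples cannot be seen in these values. The number of arrays limits the precision. Bead numbers, bead-level errors and detection p-values were not used here.

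Before the data were examined, a background set of tissue-restricted gene families, a series of gene lists with tests of their detection and of their shift per array, and a rule for naming genes were fixed. They need gene names. Of the probe numbers, 0 were found in the gene table at hand, so these parts could not be applied, and no gene is named. The part of the naming rule that needs no gene name was kept: the 10 probes with the largest SD over the 3 arrays among those above background on all 3. Of these 10 the first is given, since probe numbers without genes carry little information. One other probe is given in the closing observations and was chosen after its values were seen.

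Background was instead set from the dim peak of each array, a choice made after seeing the data. The mode of the log2 intensities was found on a histogram with steps of 0.01, smoothed with a Gaussian kernel of SD 0.05. Values below the mode were mirrored about it, and the 95th percentile of a normal distribution with that SD was the threshold. A probe was above background when it passed the threshold on all 3 arrays. This threshold describes dim probes as a whole and does not replace negative-control probes. Intensities were then taken to log2 with no offset and no further normalization. The SD over the 3 arrays, the Pearson and Spearman correlation and the number of probes at least 1.5-fold apart were computed for each pair of arrays. The error variance of each array was solved from the variances of the 3 pairwise differences, which assumes that the arrays' errors are independent of each other. The 95% confidence interval of a 3-array mean assumes normally distributed log2 values.

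The calculations were tested on simulated data with the real probes' means. For 16721 simulated probes, error SDs set to 0.1 and 0.2 were recovered as 0.10 and 0.20. Of probes set 2-fold higher on replicate 3, 94% were counted as set apart, against 40% of those set 1.5-fold higher and 0.12% of the 16521 unchanged probes. Only probes higher on replicate 3 were counted in this simulation. Its error SDs were smaller than those later estimated for replicates 1, 2 and 3 (0.11, 0.14 and 0.24). The 0.12% is therefore not an error rate for the real counts, and the 94% and 40% are not detection rates for them. Each fold was set in only a small part of the simulated probes. The background rule passed 4.9% of 35000 simulated background probes on 1 array.

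Alternatives planned before the data were examined were quantile normalization, median centring, no filter on dim probes, an offset of 16 before log2, and leaving out each replicate. Added after seeing the data were background at the 90th and 99th percentile, a fixed threshold of 8 on the log2 scale, a 2-fold limit, and removal of the median difference in 40 intensity bins. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.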

Results

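The study asked which transcripts respond when the transcriptional coactivator PGC-1α is introduced into SH-SY5Y cells by adenovirus, with a virus carrying only green fluorescent protein (GFP) as the control. SH-SY5Y is an established human neuroblastoma line of sympathetic lineage that is widely used as a neuron-like culture model, and PGC-1α is a regulator of mitochondrial gene expression. The data described here are the control arm: 3 samples labelled as replicates 1, 2 and 3 of the GFP adenovirus, each harvested 48 h after infection and each profiled on 1 bead array of biotin-labelled cRNA. Samples of the PGC-1α arm were not analysed here, so no response to PGC-1α is reported, and each value below describes the baseline and its spread over the 3 GFP arrays. Nothing in the labels says whether the replicates were separate cultures or infections, so their spread may be technical. The table names probes by manufacturer number only and does not pair them with genes, so the results are given for probes.

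The 3 arrays each held values for 48803 probes. Their intensity distributions were almost superimposed, because the values had been normalized between arrays before deposit. The median intensity was 138.7 on each array, the 95th percentile was 1772 and the highest value was 49810. Most probes lay in a narrow dim peak, with its mode at an intensity of 128.7 on replicates 1 and 2 and 128.2 on replicate 3. The spread of the dim side of this peak was 0.11 on the log2 scale on each array, which placed the 95th percentile of background at an intensity of 146.6 on replicates 1 and 2 and 145.8 on replicate 3. The mode and threshold of replicate 3 differed from the others by less than the histogram step of 0.01 on the log2 scale. That histogram started from each array's lowest value, so these differences are not a property of the samples.

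In the GFP-infected cells 16721 probes, or 34.3% of the array, were above background on all 3 arrays. A further 2442 probes (5.0%) were above background on 2 arrays, 5132 (10.5%) on 1 array, and 24508 (50.2%) on none. The background rule passed 4.9% of simulated background probes on 1 array, so many of the probes above background on 1 array alone may be background. Single arrays gave totals of 19946 probes above background on replicate 1, 19930 on replicate 2 and 20303 on replicate 3. Their similarity was set beforehand by the shared intensity distribution. Probes above background on 1 array alone numbered 1604 on replicate 1, 1750 on replicate 2 and 1778 on replicate 3, and probes below background on 1 array alone numbered 821, 983 and 638 in the same order. The slightly lower threshold of replicate 3 raises its total and affects these counts. Raising the threshold to a fixed value of 8 on the log2 scale lowered the number above background on all 3 arrays to 10102, so the size of the detected set depends on where background is set.

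Among the 16721 probes above background, the median SD over the 3 arrays was 0.12 on the log2 scale, equal to 8.8% (n = 3 arrays). The interquartile range of the SD was 0.07 to 0.19, and 5% of probes had an SD above 0.32. For the median probe, the 95% confidence interval of the 3-array mean extended 0.30 to each side on the log2 scale, a factor of 1.23. The spread changed with intensity. The median SD was 0.09 for probes with a mean log2 intensity of 7.2 to 8, reached 0.16 at 9 to 10, and was 0.11 from 13 to 16. The low SD of dim probes does not show better precision. Each value had to pass the threshold on all 3 arrays, which limits the spread near it. Background signal left in the values would also shrink the log2 differences of dim probes. An SD above 0.5 was found for 101 probes above background. Over 2 arrays at a time, the probes above background on those 2 arrays were used, so the probe sets differ slightly. The median SD was 0.08 without replicate 3 (17359 probes), against 0.11 without replicate 1 (17542 probes) and 0.10 without replicate 2 (17704 probes). These values compare with each other and not with the SD over 3 arrays, because a median SD over 2 arrays is lower at equal noise.

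Among probes above background, replicates 1 and 2 were closer to each other than either was to replicate 3. Between replicates 1 and 2, 43 of the 16721 probes above background (0.26%) differed by at least 1.5-fold, and none by 2-fold. Between replicates 1 and 3 the number was 565 (3.4%), of which 31 differed by at least 2-fold, and between replicates 2 and 3 it was 713 (4.3%), of which 49 differed by at least 2-fold. The Pearson correlation of log2 intensity across these probes was 0.994 for replicates 1 and 2, 0.987 for replicates 1 and 3, and 0.986 for replicates 2 and 3. The corresponding Spearman correlations were 0.985, 0.977 and 0.975. Over all 48803 probes, Pearson was again highest for replicates 1 and 2 (0.993, 0.990 and 0.989 in the same order). Spearman over all probes was lowest for them (0.812, 0.831 and 0.823). Among the 24508 probes below background on all 3 arrays it was also lowest for them (0.214, 0.267 and 0.248). These correlations are across probes, which are not independent replicates, and with 3 samples of 1 group no test of a single array against the others was made. An overall difference in brightness between the arrays cannot be seen in these values, because they were normalized between arrays before deposit.

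**Figure D1:**
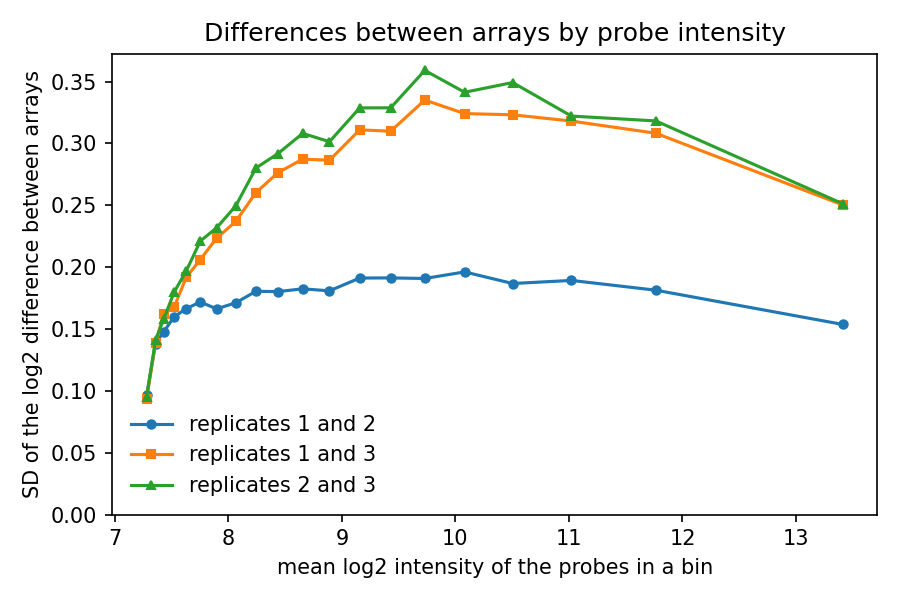
The SD of the log2 difference between each pair of GFP arrays (vertical axis, log2 units) is plotted against mean log2 intensity (horizontal axis) in 20 bins with equal numbers of the 16721 probes above background. In the dimmest bin the SDs lie between 0.094 and 0.096, and in the bin at 9.73 they are 0.19 for replicates 1 and 2, 0.34 for replicates 1 and 3 and 0.36 for replicates 2 and 3.

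The error of each array was separated by solving the variances of the 3 pairwise differences for 1 variance per array. This gave an SD of 0.11 on the log2 scale for replicate 1, 0.14 for replicate 2 and 0.24 for replicate 3. The variance of replicate 3 was 3.76 times the mean of the others, and it was the highest of the 3 in 19 of 20 intensity bins. Among the 24508 probes below background on all 3 arrays the ratio was 0.87, with SDs of 0.090, 0.093 and 0.085 for replicates 1, 2 and 3. The dim set leaves out any probe that rose above background on 1 array, and the normalization fixes its distribution, so its near-equal SDs do not show that the arrays were equally noisy. The division into 1 SD per array assumes independent errors. If replicates 1 and 2 shared a source, which the labels do not settle, the deviation they have in common would be counted under replicate 3.

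A probe was counted as set apart on an array when its value there was at least 1.5-fold above both other arrays or 1.5-fold below both. Of 362 such probes, 345 (95.3%) were set apart on replicate 3, 10 on replicate 2 and 7 on replicate 1. On replicate 3, 209 of these probes were lower than on the other arrays and 136 were higher, and at a 2-fold limit 15 were lower and 2 higher. The 10 probes above background with the largest SD were all lowest on replicate 3. The first of them, ILMN_2330112, had intensities of 3277, 3742 and 1354 on replicates 1, 2 and 3, an SD of 0.80 on the log2 scale (n = 3), and was 2.59-fold lower on replicate 3 than the geometric mean of the others. The gene it measures is not given in the sources used here.

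**Figure D2:**
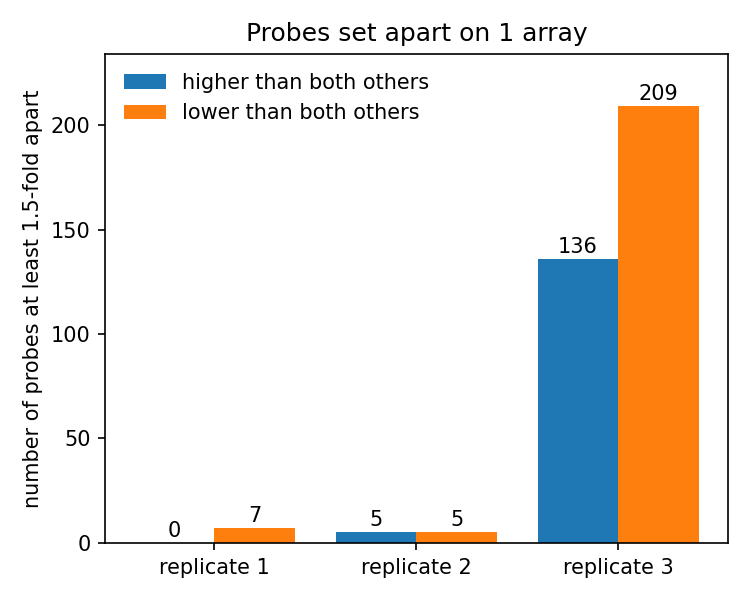
Number of probes (vertical axis) at least 1.5-fold higher or lower on 1 GFP array (horizontal axis) than on both others, among the 16721 probes above background. Replicate 3 has 136 higher and 209 lower probes, replicate 2 has 5 and 5, and replicate 1 has 0 and 7.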

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

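All thresholds on background, the 2-fold limit and the removal of intensity trends were chosen after seeing the data. Of 59 recomputed values, 48 stayed within the limits set for them and 11 moved. A change of direction could not be registered by this comparison. The limit was a factor of 1.5 for counts. For the median SD it was the SD of the medians obtained by leaving out each replicate. Those medians are over 2 arrays, so their own labels as moved or not say little about stability. With background fixed at 8 on the log2 scale, 10102 probes were above it, against 16721, 15475 at the 99th and 17695 at the 90th percentile of the dim peak. The median SD of 0.122 was 0.0934 with no filter on dim probes, which adds dim probes of low spread, and 0.141 with the fixed threshold; leaving out each replicate gave 0.0761 to 0.107, the lowest without replicate 3, and a median over 2 arrays is lower at equal noise. A 2-fold limit reduced the differing probes to 0 for replicates 1 and 2, 31 for replicates 1 and 3, 49 for replicates 2 and 3, and 17 set apart on replicate 3, by construction. With quantile normalization, median centring, no filter, the offset, the fixed threshold or the intensity trend removed, 316 to 351 probes were set apart on replicate 3, with 60.1% to 62.1% of them lower, and 6 to 12 on either other array. Quantile normalization, median centring and trend removal moved almost nothing because the arrays were already normalized, so they say little about stability. Alternatives that need gene names (a background from olfactory receptors alone, all probes of a gene, the mean over its probes, and each setting for the gene lists) were not run. No paired analysis was possible because only 1 group was analysed.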

Other observations

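The tests of additive noise, of the single probe and of probe numbers, together with the rank comparison and the split by direction of the widened differences were chosen after the result was seen; those of intensity trends and of tail shape had their predictions written before the result.

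Among probes above background, replicate 3 differed from replicates 1 and 2 more than these differed from each other. Additive noise of the same size in intensity units would matter less for bright probes, but the excess error variance of replicate 3 on the log2 scale was 3.63 times as large in the brighter 8360 probes above background as in the dimmer 8361. The background threshold limits the spread of the dimmest probes, so part of this ratio may come from the filter. A distortion that keeps the order of probes within an array, whether or not the normalization removed it, cannot change rank correlations. Among probes above background, the Spearman correlation of replicates 1 and 2 was above the higher of those with replicate 3 by 0.0084. The 95% bootstrap interval over probes (0.0076 to 0.0092, 1000 resamples) covers the sampling of probes on these arrays, not variation between arrays. Over all 48803 probes the order was reversed (0.812 for replicates 1 and 2, 0.831 for 1 and 3, 0.823 for 2 and 3). The gap therefore concerns probes above background only. Removing the intensity trend decides nothing, since the normalization had left almost none (566 probes 1.5-fold apart between replicates 1 and 3 afterwards, against 565). When the differences between replicates 1 and 2 were widened so that their median absolute deviation matched that between 1 and 3 in each bin, 531 probes were expected to be 1.5-fold apart, 246 higher and 285 lower on replicate 3, against 251 and 314 observed, and at 2-fold 14 and 16 were expected against 8 and 23. A broad widening may therefore account for the 1.5-fold count, although matching the spread sets much of that count beforehand, and the difference in direction at 2-fold was not tested. Proportional errors of labelling or RNA quality, a source shared by replicates 1 and 2, and a real difference in culture state all stay open, and no biological explanation was tested because the labels name none within the GFP group.

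One probe was bright on replicates 1 and 2 and at the bottom of replicate 3. ILMN_1659095 had intensities of 14683 and 15838 on replicates 1 and 2, ranks 251 and 230 from the top, and 94.2 on replicate 3, below that array's background threshold of 145.8. Against the threshold it was at least 101-fold lower than on replicate 1 and at least 109-fold lower than on replicate 2. By the values themselves, it was 168-fold apart between replicates 2 and 3, the largest fold of all 48803 probes. The next largest range among probes not above background on all 3 arrays was 1.72-fold. Among probes above background, the largest fold between replicates 2 and 3 was 2.83. Candidate explanations are that the transcript was absent from replicate 3, or that the probe returned no reading on replicate 3 and was placed at the bottom by the normalization. The probe was singled out by its range over the arrays, which would have been large at any dim value on replicate 3. There it ranked 1 from the bottom among the 48803 probes. Of the 24508 probes below background on all 3 arrays, 0% were lower. So low a rank is unusual for a probe at its ordinary background level, but it rests on 1 probe on 1 array. This rank was also seen before the explanations were written, so it decides for neither. The explanations cannot be told apart without bead numbers. The lowest value on replicates 1 and 2 was 90.7, below the 94.2 of this probe. If further rows entered the normalization, its rank among them is not known.

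The share of probes above background differed between blocks of 100000 consecutive probe numbers. It was 6.2% of 2498 probes in the block from 1900000 and 14.2% of 12859 in the block from 1800000, against 44.0% of 16173 in the block from 1700000 and 61.0% of 497 in the block from 2400000. The range over the blocks with at least 100 probes was 54.7 percentage points, and no permutation of the probes reached it (permutation test, 10000 permutations, p = 0.0001, the smallest they can give). What distinguishes the targets of the blocks was not tested.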
